A study of Mus musculus with 3 samples.

How the data were processed

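RNA from mouse retinas at postnatal day 12 was measured on 1-colour Agilent expression arrays, with 1 array for wild-type, 1 labelled Otx2 KI and 1 labelled Crx KO. Per the labels' protocols, retinas were dissected with forceps, total RNA was purified with QIAzol, and the RNA was amplified and labelled with the dye Cy3. The 3 genotypes were taken from the labels. KO is the usual short form for knockout and KI for knock-in, but the labels state neither the changed exons nor the locus of the Otx2 KI.

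The deposited scanner files hold intensity values for each spot as Agilent Feature Extraction 12.0.3.1 wrote them, per the file headers. Their processed signal, a Cy3 intensity after the scanner software's own background subtraction, was the value used. Per the file headers the array design refers to the mouse build mm9. All 3 arrays lay on 1 slide and were read in the same scan, so no slide or scan separates the genotypes, and position on the slide cannot be told apart from genotype. The authors' deposited value table was also read. Set against the scanner values, it held the processed signal multiplied by 1 constant per array (2.49 for wild-type, 2.54 for Otx2 KI and 2.61 for Crx KO), with column medians of 129.8, 125.7 and 135.8. Its scale is therefore linear and uncentred, and how the constants were chosen is not given in the sources used here.

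Control spots and spots marked as outliers by the scanner software were left out (136, 132 and 126 spots on the wild-type, Otx2 KI and Crx KO arrays), and replicate spots of a probe were averaged. The log2 processed signal of each array was reduced by the 75th percentile of its non-control spots (574, 564 and 570 units of signal). For printing it was put on the wild-type array's scale, which is called scaled signal here. The arrays hold 55681 probes. The files give an accession for each probe and no gene symbol, so accessions were matched without their versions to the RefSeq genes of GRCm38.p6. This named 28331 probes (50.9%) and 21366 genes, and left 27350 probes without a symbol. Because that assembly is not the build of the files, it was used only for names and for the order of genes, and none of its coordinates are printed.

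A gene was represented by its probe with the highest mean log2 signal over the 3 arrays. Probes of a gene were compared with each other, and the median SD of log2 differences between them was 0.08 to 0.10. A gene counted as measured in a comparison when its probe was well above background on both arrays. A gene well above background on 1 array only was given as an at-least fold against the higher of its own signal and the lowest scaled signal among probes well above background on the dim array (10.2, 12.4 and 8.33 for wild-type, Otx2 KI and Crx KO).

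With 1 array per genotype there is no replicate check of any difference, no test across samples was possible and no p-value is given. The number of arrays limits the precision. Genes were called by size alone, at 2-fold or more, which is 1 on the log2 scale. The scanner software's error model gave a median error of 0.20 for a log2 difference of a gene. It covers the measurement of these 3 RNA preparations and not the spread between mice. Arrays simulated with that error and no difference gave a median of 3.5 to 4 genes at 2-fold or more. Differences were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated data for the comparison of Otx2 KI with wild-type over 15743 genes, where 100% of 200 genes shifted by 2 on the log2 scale were recovered, with 2 false calls. A shift of that size lies far past the threshold of 1, so this checks the steps and does not measure recovery of differences near 2-fold.

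Before the data were examined, 24 gene lists with 321 genes were fixed, with no gene in more than 1 list. They hold photoreceptor genes, markers of the other retinal cell types, markers of tissues next to the retina, and general responses. For each list the median log2 difference was set among the medians of 10000 random lists of the same size, drawn to match its members on mean signal in 20 bins. This percentile describes these arrays and is not a p-value. Members well above background on 1 array only entered at their bound. The genes named were also fixed by rule: Crx and Otx2, the 8 genes with the largest increase and the 8 with the largest decrease among genes brighter than the median gene, the 3 largest at-least folds per direction, and up to 4 members per list with the largest differences. Clone and predicted-model names were counted but not named, and the text prints some, not all, of the genes that the rule takes. Genes named outside the rule are said to be so where they appear.

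The overlap of the mutant comparisons was set beside the product of the list sizes divided by the number of genes, and beside simulated arrays that shared the single wild-type array. The wild-type array could not be split. Alternatives fixed before the data were examined were quantile normalization, normexp background correction (limma 3.58.1 in R 4.3.3, offset 50) with either scaling, the median of well measured probes as the scale, centring on inner retina lists, no filter on dim probes, a stricter filter, the mean of a gene's probes, the authors' value table, and thresholds of 1.5-fold and 4-fold. The normexp correction had been planned on mean spot signals. The scanner files used here carry median spot signals and no column of means, so the median spot signal was used. The chromosome of the genes that differed by 2-fold or more, the same way, between 1 mutant array and both other arrays was examined after seeing the data.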

Results

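Expression was profiled in mouse retina at postnatal day 12, an age at which rods and cones are building their light-sensing outer segments. The series holds 1 wild-type array, 1 labelled Otx2 KI and 1 labelled Crx KO. Crx and Otx2 encode related homeodomain transcription factors, and Crx is a central activator of rod and cone genes. The design asks how the expression profiles of the 3 genotypes compare. On the wild-type, Otx2 KI and Crx KO arrays, 66.6%, 63.5% and 67.1% of the 59305 non-control spots were well above background, and 0 were saturated. Probes printed at 10 spots varied with a median SD of 0.063 to 0.065 on the log2 scale. There is 1 array per genotype, so every value below describes these RNA preparations, without a check between mice.

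The targeted genes were read first. Crx, on probe A_52_P656628, had a scaled signal of 9790 in wild-type, 1062 in the array labelled Otx2 KI and 7177 in the array labelled Crx KO. It was thus 9.22-fold lower in the former (log2 -3.20) and 1.36-fold lower in the latter (log2 -0.45). Otx2, on probe A_55_P1978571, read 40886 in wild-type, 63860 in Otx2 KI and 62981 in Crx KO, which is 1.56-fold and 1.54-fold higher. Crxos, the opposite-strand gene next to Crx, was 3.96-fold lower in Crx KO and 1.33-fold higher in Otx2 KI on its brightest probe. A second Crxos probe gave 3.56-fold lower and 1.35-fold higher, and the third gave log2 -0.75 and -0.71. Where the Crx probe lies relative to the changed part of either allele is not in the labels, so its signal does not check them. For that reason the mutant arrays are named by their labels throughout.

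In the array labelled Otx2 KI, the genes that make a working photoreceptor were far below wild-type. Gnat1, the rod transducin subunit, was 124-fold lower (log2 -6.95, scaled signal 96776 against 781). Opn1mw, the medium-wavelength cone opsin, was 101-fold lower (log2 -6.66, or -7.41 with its probes averaged and -5.55 with normexp background correction), and Rcvrn, which encodes recoverin, was 65.0-fold lower (log2 -6.02). Of the 15809 genes measured on both arrays, 400 were lower by 2-fold or more and 213 were higher, and 17 of the lower and 5 of the higher genes differed by at least 16-fold. A further 86 genes were at least 2-fold lower and 40 at least 2-fold higher with 1 array dim, among them Fscn2, a photoreceptor actin-bundling protein, at least 87.7-fold lower. With normexp 130 genes were higher and 282 lower. Folds that rest on a dim array were smaller, for example log2 -4.08 for Fscn2 and -1.91 for Opn1sw. Without a filter on dim probes 498 were higher and 906 lower.

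Photoreceptor lists shifted down together in Otx2 KI, by very unequal amounts. Of 16 rod phototransduction genes 15 were lower by 2-fold or more, with a median log2 difference of -1.88. They included Pde6a, the catalytic subunit of the rod phosphodiesterase (45.4-fold), Slc24a1, the rod sodium-calcium exchanger (28.4-fold), and the potassium channel gene Kcnj14 (23.5-fold). Of 14 cone phototransduction genes 8 were lower, 1 was higher and 5 were neither, with a median of -1.59. The short-wavelength opsin Opn1sw was at least 16.7-fold lower, the cone arrestin Arr3 11.0-fold lower and the cone phosphodiesterase subunit Pde6h 8.58-fold lower. Gngt2, the cone transducin gamma subunit, was the exception, at 4.38-fold higher; it was named after its value was seen. Of 25 outer segment and cilium genes shared by rods and cones 14 were lower, with a median of -1.06, among them the guanylate cyclase activator Guca1b (29.7-fold, and log2 -6.02 with its probes averaged) and the guanylate cyclase Gucy2f (16.9-fold). The medians of these 3 lists lay below those of all 10000 random lists, and across them 37 of 55 genes were lower by 2-fold or more, 1 was higher and 17 were neither.

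Genes for the photoreceptor synapse and for transcription regulators had medians below 0 too. Of 16 synapse genes 3 were lower by 2-fold or more, with a median of -0.53, below all 10000 random lists: the calcium-binding protein gene Cabp4 (10.8-fold), the complexin Cplx4 (3.65-fold) and the vesicular glutamate transporter Slc17a7 (2.13-fold, and log2 -0.98 with normexp and quantile normalization). Of 14 photoreceptor transcription regulators 11 were within 2-fold, and the median was -0.30 (-0.18 with normexp), below all but 0.02% of random lists. Both lists were mixed, with 10 synapse genes below 0 and 6 above, and 8 regulators below 0 and 6 above. The regulators that moved went opposite ways. The nuclear receptor Esrrb was 33.9-fold lower, while Rxrg, a retinoid receptor made by developing cones, was 9.37-fold higher and Samd7 3.33-fold higher. The other Rxrg probe gave log2 0.84. Nrl, the rod fate factor, had a log2 difference of -0.89.

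Large increases in Otx2 KI were also seen outside the photoreceptor lists. Col16a1, a collagen gene, read 294 in wild-type and 26926 in Otx2 KI (91.7-fold, with log2 5.52 over all its probes), and Insm2, a zinc finger gene, read 265 and 10420 (39.4-fold, with log2 3.26 on its other probe). Fabp7, a brain fatty acid binding protein, was 12.8-fold higher, the signalling ligand Wnt9a 12.8-fold, the matrix protein Smoc2 8.38-fold, and the calcium channel Cacna1h 5.56-fold. With the wild-type array dim, the keratin gene Krt90 was at least 10.4-fold higher (log2 1.21 with normexp).

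Markers of the other retinal neurons stayed near wild-type levels in Otx2 KI. Among 22 bipolar genes 21 were within 2-fold and the median was -0.16, below all but 0.09% of random lists; Lrit3, a protein needed at the synapse between photoreceptors and ON-bipolar cells, was 2.53-fold lower, but within 2-fold with normexp (log2 -0.72). Amacrine (median 0.11), horizontal (0.00) and ganglion cell (0.07) lists held 1 member past 2-fold between them, the amacrine factor Ptf1a, at least 2.49-fold higher against a dim wild-type signal but within 2-fold with normexp (log2 0.48). Muller glia genes had a median of 0.12, microglia genes 0.20 and reactive glia genes -0.07, with Lcn2 4.32-fold lower (log2 -1.35 with normexp). Markers of neighbouring tissues differed too. Pigment epithelium and melanocyte genes had a median of -0.81, lower than all 10000 random lists, with the retinoid enzyme Lrat 2.13-fold lower (log2 -0.53 with normexp) and the transthyretin gene Ttr 2.29-fold lower. Of 13 such genes 2 were lower by 2-fold or more (1 with normexp). Lens genes had a median of 0.60, higher than all random lists, with the crystallin Cryaa 3.15-fold and Crygs 2.60-fold higher, although other probes of the crystallin Crygc (2.33-fold) reached down to log2 -0.25. With normexp the lens median was 0.35, and Crygs (log2 0.76) and Crygc (0.87) were within 2-fold.

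In the array labelled Crx KO many photoreceptor genes were also below wild-type. Gnat1 was 51.3-fold lower (log2 -5.68), Rcvrn 41.2-fold (log2 -5.36) and Opn1mw 135-fold (log2 -7.08, or -5.73 with normexp). The water channel Aqp1 was 33.9-fold lower and Vtn, which encodes vitronectin, 17.6-fold lower. Of 16050 genes measured on both arrays, 550 were lower by 2-fold or more and 313 were higher, with 15 and 12 of them at 16-fold or more. Another 129 genes were at least 2-fold lower and 83 at least 2-fold higher with 1 array dim. Mc1r, the melanocortin receptor, was at least 117-fold lower, the cytokine Il7 at least 60.3-fold and Susd3 at least 50.5-fold. With normexp background correction 182 genes were higher and 328 lower, with Mc1r at log2 -3.86, Il7 at -3.20 and Susd3 at -2.70, and without a filter on dim probes 789 and 1075.

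Of the rod phototransduction genes 14 of 16 were lower by 2-fold or more in Crx KO, with a median of -1.72. Kcnj14 was 16.2-fold and Slc24a1 14.4-fold lower. Of the cone genes 8 of 14 were lower and Gngt2 was 4.11-fold higher, with a median of -1.64; Pde6h was 18.8-fold and Opn1sw at least 24.9-fold lower (log2 -1.99 with normexp). Of the shared outer segment and cilium genes 13 of 25 were lower, with a median of -1.05, and Fscn2 was 98.9-fold (log2 -3.98 with normexp) and Guca1b 22.1-fold lower (log2 -5.08 with its probes averaged). All 3 medians were lower than those of the 10000 random lists, and over the 3 lists 35 of 55 genes were lower, 1 was higher and 19 were neither. Among 16 synapse genes, Cabp4 (8.57-fold) and Cplx4 (2.75-fold) were lower and Cplx3 was 2.11-fold higher (log2 0.99 when centred on inner retina lists), with a median of -0.29, below all but 0.05% of random lists. Among 14 regulators, Esrrb (13.3-fold) and Nrl (2.02-fold, and log2 -0.89 with quantile normalization) were lower, Rxrg (9.40-fold) and Samd7 (3.40-fold) were higher, and the median was -0.20, below all but 1.49%. Rxrg again differed between probes, with 0.75 on the other.

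**Figure D1:**
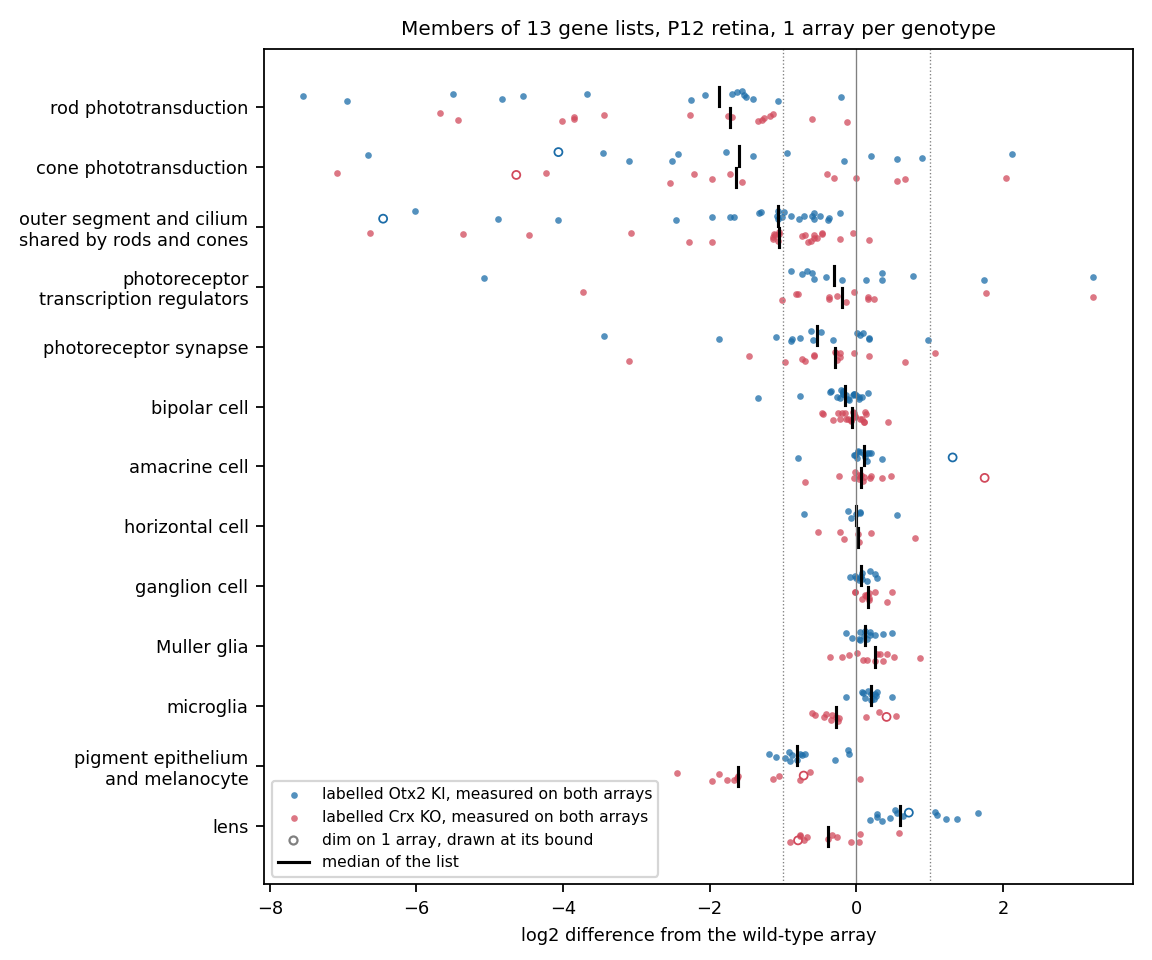
Log2 differences from the wild-type array (horizontal axis) for the members of 13 gene lists (vertical axis), in blue for the array labelled Otx2 KI and in red for the array labelled Crx KO. Each point is 1 gene, open circles are genes dim on 1 array drawn at their bound, black bars are list medians and dotted lines mark 2-fold; most rod, cone and shared outer segment genes lie below 0, down to beyond -7, with Gngt2 above 0, while most bipolar, amacrine, horizontal and ganglion cell genes lie close to 0.

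The largest increases in Crx KO included several of those seen in Otx2 KI. Col16a1 was 45.1-fold higher (log2 4.70 with its probes averaged), Insm2 31.6-fold (3.97 likewise), Smoc2 16.3-fold, Wnt9a 9.82-fold and Fabp7 9.78-fold. The transcription factor Maf was 7.27-fold higher and Ramp3, a receptor activity-modifying protein, 5.92-fold higher. With the wild-type array dim, the tissue kallikrein Klk1b27 was at least 54.2-fold, Tecta, an inner ear matrix gene, at least 50.6-fold, and Lypd11 at least 16.9-fold higher; with normexp these were log2 3.24, 3.17 and 1.38.

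Other retinal cell types again lay close to wild-type in Crx KO. All 22 bipolar genes were within 2-fold, with a median of -0.06. Amacrine, horizontal and ganglion cell medians were 0.06, 0.02 and 0.16, with Ptf1a the 1 member past 2-fold, at least 3.37-fold higher but within 2-fold with normexp (log2 0.61). The median of the Muller glia list was 0.25, above 99.96% of random lists, and the potassium channel Kcnj10 stood at log2 0.87. Reactive glia genes had a median of -0.04, with Serpina3n 10.1-fold higher (log2 1.46 with normexp) and Lcn2 3.90-fold lower (log2 -1.33 likewise), and microglia genes had a median of -0.28. Pigment epithelium and melanocyte genes were lower than in Otx2 KI: 9 of 13 were 2-fold or more below wild-type, with a median of -1.61, among them Lrat (5.45-fold) and the melanosome protein gene Pmel (3.92-fold). With normexp 6 of 13 were, with a median of -0.97, and Lrat was within 2-fold (log2 -0.82). The lens list had a median of -0.39, with 0 of its 13 members past 2-fold.

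The same genes moved in both mutant arrays more often than lists drawn independently would. Of 15743 genes measured on all 3 arrays, 344 were lower by 2-fold or more in both, where lists of 397 and 532 genes would share 13.4 by chance. Higher in both were 149 genes, where lists of 211 and 306 would share 4.10. With normexp 243 were lower and 97 higher in both, and without a filter on dim probes 631 and 258. At 2-fold 0 genes went opposite ways, which would have needed the mutant arrays to lie at least 4-fold apart. Only 14 genes were higher and 27 lower by 4-fold or more in Otx2 KI than in Crx KO. Across genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.818 and a Spearman correlation of 0.712. Both comparisons use the same wild-type array, and simulated arrays with measurement error and no effect gave a Pearson correlation of 0.494. The covariance was 0.208 against 0.0228 simulated, a difference of 0.185. The simulation holds measurement error only, so part of the excess may come from what is particular to the wild-type sample.

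**Figure D2:**
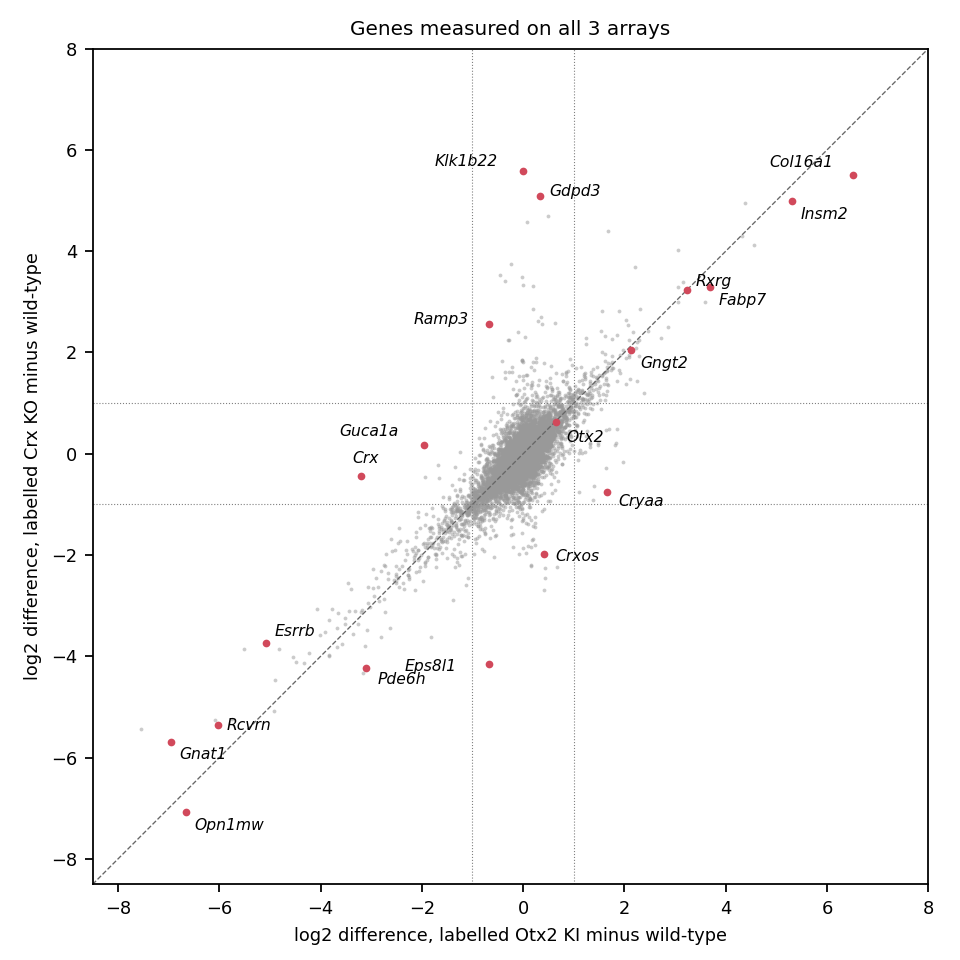
Log2 difference from wild-type in the array labelled Crx KO (vertical axis) against that in the array labelled Otx2 KI (horizontal axis), 1 point for each of 15743 genes measured on all 3 arrays, with a dashed line of equality, dotted lines at 2-fold and selected genes in red. Gnat1, Rcvrn and Opn1mw lie far down in both, Col16a1 and Insm2 far up in both, and Klk1b22, Gdpd3 and Ramp3 are higher in Crx KO alone.

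Set directly against each other, the mutant arrays differed at fewer genes. Of 15806 measured genes, 107 were higher by 2-fold or more in Otx2 KI and 102 were lower, and 53 and 67 more were at least 2-fold apart with 1 array dim. Some rod genes were lower still in Otx2 KI: Pde6a by 3.15-fold (log2 -1.66) and Gnat1 by 2.41-fold (log2 -1.27), and the rod list had a median of -0.40, below all 10000 random lists. The cone list had a median of 0.09 and the shared outer segment list -0.14. Over these lists 6 of 53 genes were lower in Otx2 KI, 1 was higher and 46 were within 2-fold. Guca1a, another cyclase activator, was 4.40-fold lower in Otx2 KI than in Crx KO, where its scaled signal of 6677 was close to the wild-type 5931. Ppef2, a phosphatase of photoreceptors, read 628 in wild-type and 633 in Crx KO and was not well above background in Otx2 KI, at least 51.0-fold lower (log2 -3.14 with normexp). Crx itself was 6.76-fold lower and Esrrb 2.56-fold lower. Otx2 differed by 1.01-fold.

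The 2 mutant arrays also differed at genes outside the photoreceptor lists. Ramp3 was 9.47-fold lower in Otx2 KI than in Crx KO, Tecta at least 41.5-fold (log2 -3.14 with normexp), and Obox6, a homeobox gene of the egg and early embryo, at least 367-fold (log2 -6.06 with normexp). Obox6 read 4558 in Crx KO and 65.6 in wild-type. It was not well above background in Otx2 KI, so the comparison by chromosome below leaves it out. Its place relative to Crx was not examined. Crxos was 5.27-fold (log2 1.57 with its probes averaged) and the chemokine Ccl27a 4.06-fold higher in Otx2 KI than in Crx KO. Ccl27a read 5478 in wild-type, 5705 in Otx2 KI and 1404 in Crx KO, so it was Crx KO that stood apart from wild-type. Lens genes were higher in Otx2 KI, with a median of 0.98 and 7 of 14 past 2-fold, and so were pigment epithelium (0.61), microglia (0.50), cell cycle (0.58) and interferon response (0.75) lists, each above all 10000 random lists, although only 2 of 13, 0 of 13, 1 of 10 and 2 of 9 of their members were past 2-fold. With normexp the medians were 0.57 for lens, with 2 of 14 past 2-fold, and 0.29, 0.45, 0.27 and 0.30 for the other lists in turn, with 0 members past 2-fold. Bipolar genes had a median of -0.12 and synapse genes -0.11. The counts at 2-fold rested on the background correction and on the filter on dim probes. With normexp they were 35 higher and 50 lower, or 34 and 53 after quantile normalization, and without the filter 394 and 581.

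Genes that stood apart on 1 mutant array were set against their chromosomes, a comparison added after seeing the data. In Crx KO 127 genes differed by 2-fold or more, the same way, from both wild-type and Otx2 KI, and some of these also differed between Otx2 KI and wild-type. Of the 127 genes 31 (24.4%) lay on the chromosome that carries Crx in GRCm38.p6. That chromosome holds 1275 of the 15743 genes measured on all 3 arrays (8.10%), so the share was 3.01 times that of all genes. The ratio was 1.88 with genes taken at 1.5-fold and 4.57 at 4-fold. Most of the 127 genes lay on other chromosomes. They made up 2.43% of the measured genes on the chromosome of Crx and 0.16% to 1.47% of those on each other chromosome, leaving out any with 3 or fewer measured genes. Of these 127 genes 11 lay within 100 measured genes of Crx, 6.78 times the share of all genes. For Otx2 KI 3 of 35 such genes were on that chromosome (8.57%), Crx among them, and of the 493 genes that moved the same way in both mutants 33 were (6.69%). The following genes were named after their values were seen. The kallikreins Klk1b22 and Klk1b3, neighbours on that chromosome, read 44.1 and 48.7 in wild-type, 44.3 and 68.7 in Otx2 KI and 2125 and 1263 in Crx KO. Gdpd3 read 28.7, 36.3 and 979, and Tescl 28.9, 30.5 and 688. Eps8l1 read 223, 139 and 12.5.

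**Figure D3:**
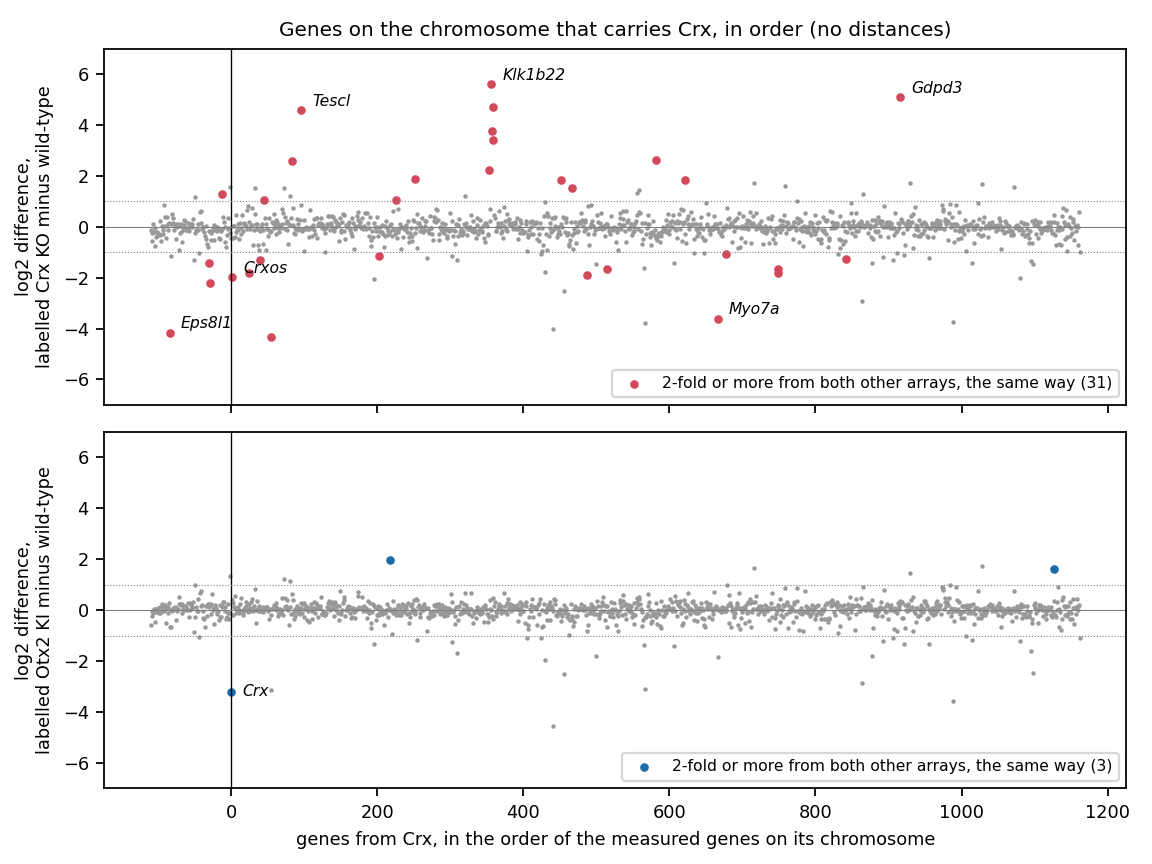
Log2 difference from wild-type (vertical axes) of the 1273 genes with a place in the order of the chromosome that carries Crx, by their distance from Crx counted in genes (horizontal axis), for the arrays labelled Crx KO (above) and Otx2 KI (below). Coloured points, 31 in Crx KO and 3 in Otx2 KI, differed by 2-fold or more from both other arrays the same way; in Crx KO they run from Eps8l1 on one side of Crx to Gdpd3 far along the other.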

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

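Probes without a gene symbol were outside every comparison by gene, and some of them differed between genotypes at 2-fold or more, which is what drew attention to them. Among those measured on both arrays, 175 were higher and 285 lower in the array labelled Otx2 KI than in wild-type, and 400 were higher and 369 lower in the array labelled Crx KO. The probe with the largest decrease was the same in both, A_55_P1985453, which the files name by an Ensembl transcript: its scaled signal was 4032 in wild-type, 68.2 in Otx2 KI (59.1-fold lower) and 75.3 in Crx KO (53.5-fold lower). The largest increase in Otx2 KI was on probe A_55_P2410106, which read 38.4 in wild-type, 539 in Otx2 KI (14.0-fold higher) and 661 in Crx KO. The largest increase in Crx KO was on probe A_30_P01027709, whose name places it on chromosome 3 between 96074625 and 96086375 in mm9, and which read 11.6 in wild-type, 6.92 in Otx2 KI and 480 in Crx KO (41.3-fold higher). These probes were not matched to a gene, and no explanation for them was tested.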

How the results depend on the processing

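The medians of the rod and cone lists stayed below 0 in both mutants under every alternative, at -1.87 or below for rods and -1.40 or below for cones in Otx2 KI, and at -1.66 or below and -1.56 or below in Crx KO. The list shared by rods and cones also stayed below 0, but its mean was further from 0 than its median (-1.71 in Otx2 KI, -1.47 in Crx KO and -0.25 between the mutants), since a few members differ by very large factors. Counts of genes moved most, in Otx2 KI against wild-type, Crx KO against wild-type and Otx2 KI against Crx KO in turn. At 1.5-fold, 578, 805 and 386 genes were higher and 1004, 1324 and 365 lower, with 396 higher and 796 lower in both mutants; at 4-fold, 35, 61 and 14 were higher and 110, 122 and 27 lower, with 27 and 86 in both. Fewer or more genes pass a higher or lower threshold by construction. Without a filter on dim probes, 498, 789 and 394 were higher and 906, 1075 and 581 lower, with 258 and 631 in both, because dim genes are then counted, and the correlation of the mutants fell to 0.698. With normexp background correction 130, 182 and 35 were higher and 282, 328 and 50 lower, with 97 higher and 243 lower in both mutants. With normexp and quantile normalization these were 129, 193 and 34 higher, 272, 311 and 53 lower, and 99 higher and 233 lower in both. The cause was not tested, though the offset of 50 draws dim signals together. The excess on the chromosome of Crx, an alternative set added after seeing the data, was 1.88 times at 1.5-fold and 4.57 times at 4-fold. Between the mutants, the amacrine median turned from -0.04 to 0.042 and the glycolysis median from -0.02 to 0.062 when centred on inner retina lists, and the glycolysis mean was 0.0036, all close to 0; the cause was not tested. Of 3718 other values for single genes and lists, 3555 stayed within their spread, 160 moved beyond it and 3 reversed, which are the ones just given. Averaging all probes of a gene moved 12 of 336 values of single genes by more than 1.5 times, Rxrg from 3.23 to 2.03 and Guca1b from -4.89 to -6.02 in Otx2 KI among them. Normexp correction moved 60, for example Egr2 from 3.06 to 1.24 in Otx2 KI, and 0 turned to the other direction. Of 144 such values at 2-fold or more 30 fell below it with normexp, against 4 or fewer with any alternative without normexp. No scaling moved the median of all genes by more than 0.087 on the log2 scale. No paired analysis was possible because each genotype has 1 array. Signal over background limits dim genes to bounds, and 1 array per genotype leaves no measure of the spread between mice.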

Other observations

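Beyond the photoreceptor genes, immediate early response genes were higher in both mutant arrays, with medians of 0.76 in Otx2 KI and 0.96 in Crx KO, both above all 10000 random lists. Of 11 genes 4 and 5 were past 2-fold. With normexp the medians were 0.54 and 0.65, with 3 and 5 past 2-fold. Between the mutants the median of this list was -0.04. Both comparisons share the single wild-type array, so anything particular to that sample, its handling included, would enter both values alike. That was not tested. The transcription factor gene Egr2 was 8.36-fold and 7.98-fold higher (log2 1.24 and 1.23 with normexp), and the phosphatase gene Dusp1 2.73-fold and 2.81-fold. Egr1, another early factor, was 3.05-fold higher in Crx KO and stood at log2 0.84 in Otx2 KI. Glycolysis genes had medians of -0.30 and -0.33, below all but 0.03% and 0.13% of random lists, and 2 of 13 were lower by 2-fold or more in each mutant: Pfkfb2, which sets the level of a glycolytic activator, 4.41-fold and 3.58-fold, and the hexokinase Hk2 4.21-fold and 3.75-fold. Tph1, the serotonin-synthesis enzyme on the pineal list, was 5.72-fold lower in both (log2 -1.22 and -1.27 with normexp), while that list's medians were -0.04 and -0.11.

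Some groups differed between the mutants. Interferon response genes had a median of -0.03 in Otx2 KI and -0.72 in Crx KO, where Usp18 was 2.60-fold lower, while Irf7 was lower in both (log2 -1.60 and -1.36). Cell cycle genes had medians of 0.02 and -0.57, with Ccnb1 2.30-fold lower in Crx KO. With normexp the Crx KO medians of these lists were -0.41 and -0.30 and 0 of their members were past 2-fold: Usp18 stood at log2 -0.53, Irf7 at -0.65 and Ccnb1 at -0.44, and Irf7 in Otx2 KI at -0.76. Cell death genes had medians of 0.11 and 0.00, with the stress factor Atf3 2.12-fold and 2.01-fold lower (log2 -0.64 and -0.66 with normexp). Red blood cell genes had medians of -0.66 and -0.56, with 0 of 7 past 2-fold, and blood vessel genes -0.22 and -0.41. Circadian clock genes had medians of 0.04 and 0.14, and genes of the sex chromosomes 0.01 and -0.05, with 0 of 4 past 2-fold. None of these differences has a replicate.

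All tests of explanations below were chosen after the results were seen, and so were the genes Rgs9 and Dct. Genes that differed by 2-fold or more, the same way, between the array labelled Crx KO and both others gathered on the chromosome that carries Crx, at 3.01 times the share among all measured genes (1.88 times at 1.5-fold and 4.57 times at 4-fold). Those set apart likewise at 2-fold on the Otx2 KI array did so at 1.06 times. Cross-hybridisation within multigene families such as the kallikreins is argued against as the whole cause, because with 1 gene kept per family the ratio was 2.82. A segment of another mouse strain carried along with the targeted allele stays open: it would gather these genes around Crx, and their share near Crx was 1.70 to 3.38 times that on the rest of the chromosome, depending on whether 200 or 50 genes were taken either side. Such a segment would not by itself account for those of the 127 genes that lie on other chromosomes, and no explanation was tested for those. Whether the mutant labels were exchanged cannot be told apart, because Crx differed by log2 -3.20 in the array labelled Otx2 KI, where it stayed well above background, and by -0.45 in Crx KO, Crxos was 1.33-fold higher and 3.96-fold lower, and the place of the Crx probe relative to either changed allele is not known. An effect of the genotype itself on these genes was not tested.

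Photoreceptor genes were lower in both mutants by very different factors, for example Gnat1 by 124-fold and Rgs9 by 1.15-fold in Otx2 KI. A smaller share of photoreceptor cells would lower genes made only by them by about 1 factor. The SD of log2 differences over the 3 lists was 1.91 or more in each mutant. That SD restates the unequal factors already seen, and pooling rod and cone genes or genes also made elsewhere can widen it. Over the rod list alone it was 2.23 in Otx2 KI and 1.71 in Crx KO. As far as its members are made by rods alone, this argues against a smaller share as the whole cause, but it is no separate test. Some loss of cells on top of other changes is not excluded. Scaling of the arrays is argued against too, since the rod median stayed at -1.66 or below in both mutants under every scaling, normalization and background correction. An effect of the genotypes on transcription of these genes stays open and was not tested beyond these arrays.

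The pigment epithelium and melanocyte list had a median below 0 in both mutants, with all 13 measured members well above background in wild-type retina. Lower by 2-fold or more were 2 of 13 in Otx2 KI (1 with normexp) and 9 of 13 in Crx KO (6 with normexp). Dct, for example, read 10662 in wild-type, 5706 in Otx2 KI and 3353 in Crx KO. Less of every outside tissue carried over at dissection would lower the lens list too. In Otx2 KI that list was higher, at a median of 0.60, which argues against it only as far as the list reflects lens carried over. Whether retinal cells gave part of that signal was not tested, and some members were dim in wild-type (Cryba1 28.0, Crygs 53.8). Of the 14 lens members 5 were higher by 2-fold or more in Otx2 KI (median 0.35 and 1 of 14 with normexp). The red blood cell (-0.66) and blood vessel (-0.22) medians were below 0 there, with 0 of 7 and 0 of 11 members past 2-fold, so less of some tissues is not excluded. For Crx KO less of every outside tissue stays open, as the lens, red blood cell and blood vessel medians were -0.39 (-0.18 with normexp), -0.56 and -0.41. Less pigment epithelium alone would lower its genes by about 1 factor, and in Otx2 KI the SD of the list was 0.35, within the bound of 0.5 set for that, so such carry-over stays open there. In Crx KO the SD was 0.68, between the bounds for a common factor and for separate ones, so carry-over cannot be told apart from a change in the cells. An effect of the genotype on these genes stays open and was not tested.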
